A study of Mus musculus with 4 samples.

How the data were processed

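Elavl HITS-CLIP was performed on UV-irradiated brain tissue and cell line samples of mouse. Per the labels, RNA was partly digested with RNase, linkers were added at both ends of the bound fragments, the one at the 5′ end being degenerate, and the products were amplified by PCR. The labels give 3 cortex samples, with a degenerate linker of 25 nt, and 1 N2A sample, with a linker of 7 nt. Linker design therefore differed with the group. The cortex samples share 1 peak list whose name carries the words for 2 months, a term the labels do not explain, and the N2A sample has 1 list of its own. The antibody, the age of the mice and the number of reads are not given in the sources used here.

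Each deposited list gives chromosome, start, end, strand, a label and a p-value per peak. The p-value was made by the authors' peak calling, and the deposited values run from 0 to just under 0.1. Whether it was adjusted for multiple testing, the peak caller, its filters, and whether reads of the cortex samples were merged before calling are not given in the sources used here. The submitters' processing notes name the aligner Novoalign, with no version, and the human build hg19. Chromosome and scaffold names are those of mouse, so the build was checked against the RefSeq gene table of GRCm38.p6. Of the cortex and N2A peaks, 94.9% and 94.6% touched a coding gene span, against 39.3% to 44.8% after shifting the peaks by 1, 3 or 5 Mb, and coordinates were read as GRCm38. Coordinates are printed as deposited, and whether they count from 0 or from 1 is not stated.

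The strength of a peak was its p-value within its own list. The cortex list had a median p of 0.00972, 65 values of exactly 0, and 77.2% of peaks under 0.05. The N2A list had a median p of 0.00605, 8 values of 0, and 79.7% under 0.05. All deposited peaks were used. Because the lists hold no tag counts, depth is unknown, and no value per sample, replicate agreement or replicate spread could be computed. Intervals for shares of peaks are Wilson 95% intervals. Intervals for ratios of counts come from exact Clopper-Pearson 95% intervals of the share on 1 side, and that for the difference of shares combines the Wilson limits. These cover counting error only, and peaks are not replicates.

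The reference held spans, types and names of 49997 genes, 21900 of them coding, without strand, exons, untranslated regions or sequence. A peak with at least 50% of its length in 1 small RNA gene of at most 400 nt went to that gene. Any other peak went to the single coding gene whose span it touched, then to a single other gene, and otherwise to the class of several genes or of none. Strand was not used, so a coding gene also takes the peaks of noncoding genes that lie within it. The strand of a gene was taken as that of most of its peaks. In 5596 genes with at least 3 peaks, 99.6% of peaks lay on the majority strand, and in 95 genes fewer than 90% did. Distance to the gene end was measured on each peak's own strand to the end of the span, for coding genes.

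The planned shares of introns, coding exons and 3′ UTRs, the position within 3′ UTRs and the sequence motifs needed exons or a genome and were not run. Distance to the gene end, with a window of 5 kb, replaced them. It was chosen after the lists had been seen. Its strand definition was changed after values had been seen, from peaks on the majority strand of genes with at least 3 peaks to each peak's own strand in all coding genes. Both the strand and the set of genes changed with it, from 5476 to 8439 genes in cortex and from 2461 to 2946 in N2A, and the shares moved from 18.1% to 19.7% and from 79.5% to 79.8%. The gene groups, the tests on them, the peak overlap and the rule for named genes were fixed before the data were examined.

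Gene groups were 29 hand-written lists with 621 entries, all matched to the reference. They covered the ELAV-like family, splicing and decay factors, synaptic, channel and cytoskeletal genes, immediate early genes, AU-rich ELAVL1 targets, cell cycle, sympathoadrenal, chromatin, ubiquitin, translation, ribosomal and oxidative phosphorylation genes, markers of 6 brain cell types, and noncoding RNAs. For each list, 27 groups of coding genes were compared with all other coding genes, and all 29 groups were compared in N2A against cortex among genes with a peak in either list. Tests were two-sided Fisher's exact tests over genes, adjusted by Benjamini-Hochberg over the groups, with a threshold of 0.05. They describe the lists, because genes, not samples, are counted. Odds ratios had 0.5 added to each count. Each group was also placed among 10000 random lists matched on gene length in 10 classes, or on cortex peak strength in 10 classes with genes lacking cortex peaks kept as a class of their own. Gene span length stood in for the planned 3′ UTR or transcript length, which the reference does not give.

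Overlap meant at least 1 nt on the same strand. It was compared with 1000 random placements between the outermost peaks of a gene, as planned, and with placements over the whole gene or its last 5 kb and peaks moved by fixed distances, which were added after the lists had been seen. The mean difference per gene between lists had an interval from 1000 bootstraps over genes. The alternatives tried were the stronger 50% of each list, the strongest cortex peaks as many as N2A had, each gene counted once, other overlap rules, genes with at least 2 N2A peaks, other windows, peaks near the gene end alone, and every gene touched by a peak.

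Named genes were the 10 with the strongest peaks in cortex, in N2A, in N2A without a cortex peak, in cortex without an N2A peak, and shared by N2A strength. Ties were ordered by number of peaks and then by symbol. Up to 4 members of each group with the strongest peak, and all ELAV-like genes, were added. Genes named for having the most peaks, for peaks past the gene end, for more N2A than cortex peaks or for peaks on both strands were chosen after their values were seen, as were group members named as exceptions or for their number of peaks.

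Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. The procedure was tested on simulated data with 21900 coding genes. Groups simulated with 90% of members bound, against 38.5% of other genes, were called in 99.3% of 450 cases. Unchanged groups were called in 0.941% of 850. Genes were drawn independently, the smallest groups were left out, and the lower share of bound genes in N2A was not simulated. Of 3000 simulated peaks, 0 had a wrong shared state. In a separate set planted in coding genes, 1931 peaks were given 1 gene, and for 99.9% of these it was their own. Planted peaks that were not given 1 gene were left out of that share, so it does not count them as failures. Of the 1930 peaks given their own gene, 100% got the right distance. Shared peaks were slightly moved cortex peaks, unshared ones lay on no real chromosome, and distances were planted with the formula that read them. The results for shared state and distance therefore check the code alone and could hardly fail. No input or control list was analysed here.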

Results

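Sites where Elavl proteins touched RNA were mapped by HITS-CLIP in mouse cortex and in N2A cells, a mouse neuroblastoma line. In this assay ultraviolet light crosslinks a protein to the RNA it touches, the protein is immunoprecipitated, and the RNA fragments left on it after partial RNase digestion are sequenced. The family consists of Elavl1 (HuR), made in most cell types, and Elavl2, Elavl3 and Elavl4, made mainly in neurons, and its members bind U-rich and AU-rich RNA. The labels do not say which of these proteins the antibody recognised. There were 3 cortex samples and 1 N2A sample, and each group was represented by 1 list of peaks 50 to 51 nt wide. The cortex list held 97775 peaks and the N2A list 7335, a ratio of 13.3. Each peak carried a p-value from the authors' peak calling and no read count, so the sequencing depth is unknown. No value belonged to a single sample, so no spread between replicates could be computed, and intervals for shares of peaks are Wilson 95% intervals for counting error alone. Reads made by PCR are not independent molecules. The p-values of the lists were used to rank peaks within a list and were not compared between lists.

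Elavl peaks in cortex lay mostly within the spans of protein-coding genes, as did those in N2A. The coding share was 93.2% (93.0 to 93.3) in cortex and 91.7% (91.1 to 92.3) in N2A. Of the genes that were given peaks, 94.2% in cortex and 96.9% in N2A were coding. Peaks in several genes or in none drop out of these gene shares, so they have another base than the shares of peaks. Genes for long noncoding RNAs held 1.54% of cortex peaks and 0.90% of N2A peaks. Small RNA genes of at most 400 nt held 60 cortex peaks (0.0614%) and 24 N2A peaks (0.327%), and small nucleolar RNAs made up 37 and 15 of them. Pseudogenes and other gene types held 0.148% and 0.600%. Peaks in several overlapping genes made up 1.84% and 2.75%, and peaks outside every gene span 3.24% and 3.71%. The cortex list assigned peaks to 8961 genes, 8439 of them coding, with a median of 4 peaks per gene. The N2A list assigned peaks to 3040 genes, 2946 of them coding, with a median of 1.

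In cortex, the lowest p, listed as 0, was shared by the strongest peaks of 60 genes, and ties were ordered by the number of peaks. Fgf14, an intracellular partner of voltage-gated sodium channels, came first with 603 peaks. Its strongest peak lay on the minus strand of chromosome 14 at 124577437 to 124577488 (GRCm38), 603 kb from the end of a 703 kb gene. Syt1, the calcium sensor of synaptic vesicle release, had 162 cortex peaks, the strongest on the minus strand of chromosome 10 at 108499242 to 108499293, 1.62 kb from the gene end. That Syt1 peak also lay in the span of another gene, Gm36601. Ank3, the ankyrin that organises the axon initial segment, had 96, with the strongest at 70024280 to 70024331 on the plus strand of chromosome 10. Qk, an RNA-binding regulator of myelin transcripts, had 94, and Gpm6a, a neuronal membrane glycoprotein, had 80, the strongest at 55059226 to 55059277 on the plus strand of chromosome 8. Rian, a long noncoding RNA of an imprinted region, had 46 peaks, the strongest at 109661170 to 109661221 on the plus strand of chromosome 12. Dclk1, a microtubule-associated kinase, had 44, Pafah1b1, the lissencephaly protein Lis1, had 40, Sv2b, a synaptic vesicle glycoprotein, had 40, and Snap25, the membrane SNARE of synaptic release, had 37. The strongest Snap25 peak lay on the plus strand of chromosome 2 at 136781437 to 136781488, 0.966 kb from the gene end. Of these 10 genes, Syt1, Qk, Dclk1, Pafah1b1 and Snap25 also had N2A peaks.

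Long genes held the greatest numbers of cortex peaks. Kcnip4, a potassium channel partner, had 812, Pcdh9, a protocadherin, 644, and Ptprd, a receptor phosphatase, 642 (these genes were chosen after their counts were seen). The 30 genes with the most peaks held 12191 of them, 12.5% of the list, and the shortest was 486 kb long. Only 4 of the 30 had an N2A peak, namely the splicing regulator Rbfox1 (1 peak), Cntnap2 (1), Rims2 (3) and Auts2 (4). Across genes, the number of peaks and gene length had a Spearman correlation of 0.587 in cortex and 0.132 in N2A. Genes are not independent replicates. Exactly 1 peak was found in 1548 of 3040 genes in N2A, against 2324 of 8961 in cortex. The N2A counts are therefore largely tied, and the 2 correlations are not directly comparable.

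The next question was which functional groups of genes carried peaks in each list, against 38.5% of all protein-coding genes in cortex and 13.5% in N2A. In cortex 22 of 27 gene groups held more genes with peaks than other coding genes did, by two-sided Fisher's exact tests over genes with Benjamini-Hochberg adjustment over the groups. Every member of 5 groups had a cortex peak. These were the ELAV-like genes themselves (4 of 4, exact adjusted p = 0.0283), hnRNP and SR splicing factors (30 of 30, adjusted p = 4.92e-12), chromatin regulators (30 of 30, with the same adjusted p), translation factors (23 of 23, adjusted p = 1.58e-09) and genes of glutamate synthesis and transport (15 of 15, adjusted p = 1.37e-06). The ELAV-like call ended with peaks within 5 kb of the gene end alone (odds ratio 5.61, exact adjusted p = 0.0929). Genes of the presynaptic vesicle machinery and of voltage-gated ion channels each had peaks in 28 of 29 members (exact adjusted p = 3.03e-10). Cacna1a, the pore of P/Q-type calcium channels, had 42 cortex peaks (best peak p of 3.17e-280), and Cacna2d1, a calcium channel auxiliary subunit, had 90 (best peak p of 2.43e-252). Kcnd2, an A-type potassium channel, had 472. Peaks were found in 16 of 17 ionotropic glutamate receptor genes (exact adjusted p = 4.90e-06), Grin2d being the exception. The AMPA receptor subunit Gria2 had 81 peaks and the NMDA receptor subunit Grin2b had 90.

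GABA signalling genes had cortex peaks in 18 of 19 members (exact adjusted p = 1.03e-06), axon growth and actin genes in 28 of 30 (adjusted p = 1.91e-09), and microtubule and neurofilament genes in 26 of 28 (adjusted p = 9.63e-09). Postsynaptic scaffold and plasticity genes had them in 24 of 28 (exact adjusted p = 9.88e-07), ubiquitin and proteasome genes in 23 of 25 (adjusted p = 1.18e-07), and mRNA decay factors in 24 of 27 (adjusted p = 2.48e-07). For neuronal splicing regulators the count was 19 of 21 (exact adjusted p = 2.35e-06). Celf2, one of them, had 353 cortex peaks with a best p of 4.70e-236. Immediate early genes, which neuronal activity induces, had peaks in 16 of 20 members (exact adjusted p = 0.000418), oxidative phosphorylation genes in 20 of 29 (adjusted p = 0.00151), and AU-rich mRNAs described as ELAVL1 targets in 15 of 24 (adjusted p = 0.0272). Cell cycle genes (9 of 31, exact adjusted p = 0.38), cytosolic ribosomal protein genes (12 of 42, adjusted p = 0.232) and sympathoadrenal genes (7 of 18, adjusted p = 1) did not pass the test. In the stronger 50% of the list cell cycle (exact adjusted p = 0.0130) and ribosomal protein genes (adjusted p = 0.0230) passed as lower. The ribosomal protein genes are short. Random lists of the same gene lengths had peaks in a mean of 14.95% of members, against 28.6% of the ribosomal genes, which placed them at percentile 98.8.

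Markers of several brain cell types were among the genes with cortex peaks. Peaks lay in 13 of 14 excitatory cortical neuron markers (exact adjusted p = 6.65e-05), 11 of 14 interneuron markers (adjusted p = 0.00546), 12 of 14 astrocyte markers (adjusted p = 0.000642) and 10 of 14 oligodendrocyte markers (adjusted p = 0.0292). Among excitatory neuron markers, Camk2a, a synaptic kinase, had 11 peaks with a best p of 1.19e-279. Among interneuron markers, Pvalb, a calcium buffer of fast-spiking cells, had 2 peaks with a best p listed as 0. Glial markers included Slc1a2, the main astrocyte glutamate transporter, with 17 peaks, and the myelin genes Mbp with 11 and Mobp with 12, and for each of these genes the best p was listed as 0. Of the microglia markers 1 of 12 had a cortex peak (odds ratio 0.208, exact adjusted p = 0.0426). The microglia call ended with the stronger 50% of the list (odds ratio 0.291, exact adjusted p = 0.130) and when each peak counted for every gene it touched (odds ratio 0.345, adjusted p = 0.164). It held with peaks near the gene end alone (odds ratio 0.0960, exact adjusted p = 0.0304). Endothelial markers had peaks in 4 of 10 genes (exact adjusted p = 1). Among random lists of matched gene length, the ELAV-like genes lay at percentile 90.9, the other 21 groups with more peaks at percentiles 98.7 to 100, and microglia markers at 2.72. Expression was not measured, so the background of all coding genes includes genes that these samples may not transcribe.

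In N2A cells a lowest p, listed as 0, was shared by the strongest peaks of 8 genes. Map1b, a microtubule-associated protein of growing axons, led with 18 peaks, the strongest at 99423965 to 99424016 on the minus strand of chromosome 13, 2.53 kb from the gene end. Lrrc58, a leucine-rich repeat protein, followed with 12, the strongest at 37883731 to 37883782 on the plus strand of chromosome 16. That Lrrc58 peak also lay in the span of another gene, Gm15725. Atp2a2, the calcium pump of the endoplasmic reticulum, had 7, and its strongest peak, at 122456985 to 122457036 on the minus strand of chromosome 5, had the same coordinates in both lists. The others with a p of 0 were Scd2, a fatty acid desaturase, Actb, encoding beta-actin, Tubb5, a beta-tubulin, Sec61a1, a subunit of the protein translocation channel, and Rn18s-rs5, a ribosomal RNA-like sequence. Next came Ywhaz, a 14-3-3 protein (best peak p of 1.91e-300), and Cfl1, the actin-severing protein cofilin (best peak p of 2.26e-287). All 10 genes also had cortex peaks.

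Peaks in N2A were more frequent than among other coding genes in 14 of 27 gene groups, and less frequent in 0. The hnRNP and SR splicing factors had the smallest adjusted p, with peaks in 28 of 30 members (exact adjusted p = 3.22e-21), where Hnrnpf and Hnrnpr were the exceptions. Srsf1, an SR protein, had 6 N2A peaks (best peak p of 6.42e-102), and Hnrnpu, a nuclear scaffold protein, also had 6 (best peak p of 1.66e-39). Next by adjusted p were translation factors (17 of 23, exact adjusted p = 9.01e-10), mRNA decay factors (18 of 27, adjusted p = 2.48e-09), chromatin regulators (18 of 30, adjusted p = 2.29e-08) and neuronal splicing regulators (13 of 21, adjusted p = 1.76e-06). Eif4g2, a translation initiation factor, had 5 N2A peaks (best peak p of 4.14e-54), and Cnot6l, a deadenylase of the CCR4-NOT complex, had 13 (best peak p of 2.12e-29). The RNA-binding splicing regulator Celf1 had 10 (best peak p of 7.44e-104). Ubiquitin and proteasome genes had N2A peaks in 14 of 25 members (exact adjusted p = 2.87e-06), axon growth and actin genes in 15 of 30 (adjusted p = 6.68e-06), presynaptic genes in 13 of 29 (adjusted p = 0.000128) and AU-rich ELAVL1 targets in 11 of 24 (adjusted p = 0.000353).

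Sympathoadrenal and neuroblastoma genes had N2A peaks in 9 of 18 members (exact adjusted p = 0.000593). Gata2, a transcription factor of the sympathoadrenal lineage, had 4 N2A peaks (best peak p of 1.71e-21). Lin28b, a repressor of let-7 microRNA processing, had 4 as well (best peak p of 9.77e-30). All 4 ELAV-like genes had N2A peaks (exact adjusted p = 0.000802), as did 11 of 28 microtubule and neurofilament genes (adjusted p = 0.00136), 6 of 15 genes of glutamate synthesis and transport (adjusted p = 0.0207) and 7 of 20 immediate early genes (adjusted p = 0.0239). Groups that did not pass were cell cycle genes (9 of 31, exact adjusted p = 0.0524), postsynaptic genes (8 of 28, adjusted p = 0.0756), GABA signalling genes (3 of 19, adjusted p = 0.793), oxidative phosphorylation genes (5 of 29, adjusted p = 0.714) and ribosomal protein genes (6 of 42, adjusted p = 0.853). The cell cycle group passed with peaks near the gene end alone (exact adjusted p = 0.0143) and when each peak counted for every gene it touched (adjusted p = 0.00187). Ionotropic glutamate receptors (0 of 17, exact adjusted p = 0.243), voltage-gated channels (2 of 29, adjusted p = 0.538) and interneuron markers (0 of 14, adjusted p = 0.341) did not pass either. The same held for oligodendrocyte markers (0 of 14, exact adjusted p = 0.341), astrocyte and excitatory neuron markers (1 of 14 each, adjusted p = 0.793), microglia markers (1 of 12, adjusted p = 1) and endothelial markers (0 of 10, adjusted p = 0.509). Among random lists of matched gene length the 14 groups that passed lay at percentiles 97.2 to 100. Some groups that did not pass also lay at the extremes. Cell cycle genes lay at 99.2 and ribosomal protein genes at 98.3, whereas ionotropic glutamate receptors lay at 0.74 and voltage-gated channels at 2.81.

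**Figure D1:**
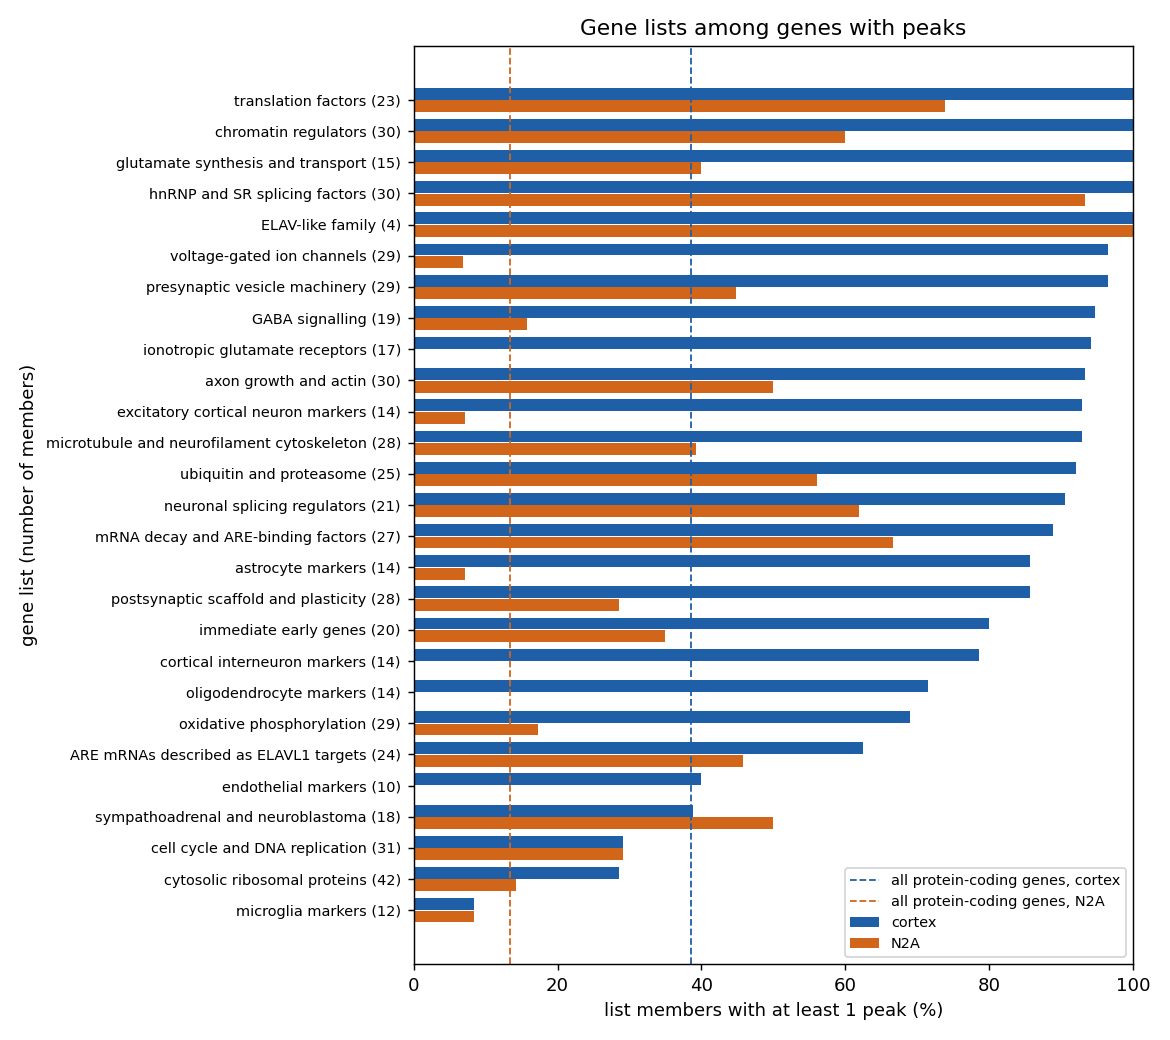
Percent of each gene group's members with at least 1 Elavl peak in cortex and in N2A, as bars from 0 for 27 groups of protein-coding genes, with dashed lines at the shares of all coding genes. Bars for hnRNP and SR splicing factors reach 100% in cortex and 93.3% in N2A, whereas ionotropic glutamate receptors reach 94.1% in cortex and 0% in N2A.

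The ELAV-like genes carried Elavl peaks in both lists. Elavl1 had 11 cortex peaks (best peak p of 9.06e-181) and 13 N2A peaks (best peak p of 2.74e-80). Its strongest peaks lay at 4288534 to 4288585 in cortex and at 4288277 to 4288328 in N2A, both on the minus strand of chromosome 8. Elavl3 had 19 cortex peaks and 2 N2A peaks, and its strongest peaks overlapped, at 22015939 to 22015990 and at 22015922 to 22015973 on the minus strand of chromosome 9. Elavl2 had 39 and 5, with the strongest at 91250802 to 91250852 and at 91251774 to 91251824 on the minus strand of chromosome 4. Elavl4 had 9 and 4, with the strongest at 110204262 to 110204313 and at 110204943 to 110204993 on the same strand of that chromosome.

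Cortex and N2A were compared to ask which bound genes the brain tissue and the neuronal tumour line shared. Of the coding genes with N2A peaks, 2689 (91.3%) also had cortex peaks, which was 31.9% of the coding genes with cortex peaks. Independent lists of these sizes would share 1135 of the 21900 coding genes (odds ratio 24.0, Fisher's exact p too small to be represented and written as 0). Expression was not measured, and this background includes genes that neither sample may transcribe. Genes transcribed in both could therefore raise the overlap without any preference in binding. Cortex peaks alone were found in 5750 coding genes and N2A peaks alone in 257. Itpr1, the calcium release receptor abundant in Purkinje cells, had 29 cortex peaks and 0 in N2A, with its strongest at 108550897 to 108550948 on the plus strand of chromosome 6. Other genes with a cortex p of 0 and 0 N2A peaks were Fgf14, Ank3, Gpm6a, Rian and Sv2b, named above, the reticulon Rtn1 (24 cortex peaks), Slc1a2 (17), the calcium pump Atp2b2 (16) and Trappc9, a subunit of a vesicle tethering complex (15). The strongest Trappc9 peak, at 72808801 to 72808852 on the minus strand of chromosome 15, also lay in the imprinted noncoding gene Peg13. With a cortex list cut to its strongest peaks, as many as N2A had, 1501 coding genes were shared, 51.0% of those with N2A peaks (odds ratio 13.9).

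Genes with N2A peaks and 0 cortex peaks were led by Ranbp1, a cofactor of Ran-dependent nuclear transport, whose 1 peak lay at 18239990 to 18240041 on the minus strand of chromosome 16 (peak p of 2.97e-67). Ddr2, a collagen receptor kinase, had 5 peaks (best peak p of 8.75e-53), and Ier2, an immediate early gene, had 1 (peak p of 2.05e-47). Slc10a4, a vesicular transporter of the bile salt transporter family, had 1 peak (peak p of 1.07e-34), and Slc35g1, a membrane protein of the solute carrier family, had 2 (best peak p of 2.77e-29). Fads2, a fatty acid desaturase, had 2 (best peak p of 9.91e-29). Insm1, a zinc finger transcription factor of neuroendocrine cells, had 1 peak at 146224428 to 146224479 on the plus strand of chromosome 2 (peak p of 5.53e-28). Gdf15, a stress-induced cytokine, had 1 (peak p of 3.29e-27), Rad18, a ubiquitin ligase of DNA damage tolerance, had 2 (best peak p of 1.38e-25), and Baiap2l1, an adaptor of membrane curvature and actin, had 4 (best peak p of 6.29e-23).

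Among the 9262 genes with a peak in either list, 32.8% had an N2A peak, and 9 of 29 gene groups had N2A peaks more often than the other genes. The hnRNP and SR splicing factors led, with N2A peaks in 28 of 30 genes (odds ratio 23.5, Fisher's exact adjusted p = 1.54e-10). Translation factors followed (17 of 23, odds ratio 5.54, exact adjusted p = 0.000931), and then mRNA decay factors (18 of 25, odds ratio 5.07, adjusted p = 0.00112). Neuronal splicing regulators (13 of 19) and chromatin regulators (18 of 30) each had an adjusted p of 0.0114. Sympathoadrenal genes had N2A peaks in 9 of 12 (exact adjusted p = 0.0123), AU-rich ELAVL1 targets in 11 of 16 (adjusted p = 0.0168), ELAV-like genes in 4 of 4 (adjusted p = 0.0336) and ubiquitin and proteasome genes in 14 of 24 (adjusted p = 0.0379). Of the 12 sympathoadrenal genes, 5 entered the comparison through N2A peaks alone, and 4 of the 7 with cortex peaks had N2A peaks. Ccnd1, a cyclin of cell cycle entry among the AU-rich targets, had 2 cortex peaks (best peak p of 0.00803) and 4 N2A peaks (best peak p of 1.92e-67). Myc, a growth-promoting transcription factor, had 4 N2A peaks (best peak p of 2.28e-09).

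Receptor and channel genes stood on the other side. Ionotropic glutamate receptors had N2A peaks in 0 of 16 genes (odds ratio 0.0619, exact adjusted p = 0.0114), voltage-gated ion channels in 2 of 28 (odds ratio 0.192, adjusted p = 0.0114) and interneuron markers in 0 of 11 (odds ratio 0.0888, adjusted p = 0.0494). The channel genes with N2A peaks were Cacna1c, the L-type calcium channel (3 peaks, best peak p of 6.72e-05), and Kcnj6, an inward rectifier potassium channel (1 peak, p of 0.00545). The strongest Cacna1c peak of each list also lay in the span of another gene, Gm50599. Gria3, an AMPA receptor subunit, had 32 cortex peaks and 0 in N2A, and Kcnma1, the large-conductance calcium-activated potassium channel, had 97 and 0. Gad2, a GABA-synthesising enzyme of interneurons, had 5 and 0. Among random lists matched on cortex peak strength, the receptors lay at percentile 0.005, the channels at 0 and the interneuron markers at 0.14. Groups that did not pass the test also lay low, with oligodendrocyte markers at 0.03, GABA signalling genes (3 of 18, exact adjusted p = 0.302) at 0.175, excitatory neuron markers at 0.27, astrocyte markers at 0.825 and postsynaptic genes at 2. Among the 9 groups with more N2A peaks, the strength-matched percentile was 100 for hnRNP and SR genes. It was 95.26 for ELAV-like genes, 94.95 for neuronal splicing regulators and 84.0 for ubiquitin and proteasome genes. The rest of the 9 lay between 97.7, for sympathoadrenal genes, and 99.955, for translation factors. Expression in N2A was neither measured nor matched, so genes without N2A peaks may not be transcribed there. These comparisons therefore do not separate binding from expression.

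The other 17 groups did not pass in this comparison, and their adjusted p-values from Fisher's exact tests stand in brackets. Oligodendrocyte markers had N2A peaks in 0 of 10 genes (0.0816), astrocyte markers in 1 of 12 (0.192), excitatory neuron markers in 1 of 13 (0.133), endothelial markers in 0 of 4 (0.409), and microglia markers in 1 of 1 (0.414). Postsynaptic genes had N2A peaks in 8 of 24 (1), presynaptic genes in 13 of 28 (0.239), microtubule genes in 11 of 26 (0.409) and axon growth genes in 15 of 29 (0.0937). Genes of glutamate synthesis and transport had them in 6 of 15 (0.654), immediate early genes in 7 of 17 (0.521), ribosomal protein genes in 6 of 14 (0.493) and oxidative phosphorylation genes in 5 of 20 (0.681). Cell cycle genes had them in 9 of 15 (0.0948), and 6 of these had N2A peaks alone, among them the replication helicase subunit Mcm2 (best peak p of 4.90e-14). Long noncoding RNAs had N2A peaks in 4 of 11 (0.785) and small noncoding RNAs in 3 of 4 (0.182). Meg3, an imprinted long noncoding RNA, had 16 cortex peaks and 0 in N2A. Rny3, a Y RNA that binds the Ro protein, had its strongest peaks at 47781664 to 47781715 in cortex and at 47781667 to 47781718 in N2A, on the plus strand of chromosome 6.

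Several of these calls changed under other settings. Against the strongest cortex peaks, as many as N2A had, 3 groups were higher in N2A, namely hnRNP and SR splicing factors (odds ratio 8.59, exact adjusted p = 0.00196), mRNA decay factors (5.56, adjusted p = 0.0335) and translation factors (5.25, adjusted p = 0.0489). The calls for ELAV-like genes (odds ratio 4.04, exact adjusted p = 0.429), neuronal splicing regulators (1.35, adjusted p = 0.681), AU-rich targets (3.45, adjusted p = 0.240), sympathoadrenal genes (8.54, adjusted p = 0.140), chromatin regulators (2.38, adjusted p = 0.267) and ubiquitin genes (1.18, adjusted p = 0.836) ended. Fewer genes entered that comparison, and every odds ratio stayed above 1. In that comparison 8 groups were lower in N2A, with GABA signalling (odds ratio 0.135, exact adjusted p = 0.00183), postsynaptic genes (0.244, adjusted p = 0.00318) and markers of excitatory neurons (0.0703, adjusted p = 0.00129), astrocytes (0.103, adjusted p = 0.0139) and oligodendrocytes (0.0262, adjusted p = 0.000773) added. When genes needed at least 2 N2A peaks, the lower calls for glutamate receptors (odds ratio 0.153, exact adjusted p = 0.190), channels (0.275, adjusted p = 0.176) and interneuron markers (0.219, adjusted p = 0.381) ended, while receptors and interneuron markers still had 0 members with N2A peaks. The higher calls for sympathoadrenal (4.29, exact adjusted p = 0.0760), chromatin (2.60, adjusted p = 0.0760) and ubiquitin genes (2.78, adjusted p = 0.110) ended as well. With the stronger 50% of each list the calls for ubiquitin genes (odds ratio 1.29, exact adjusted p = 0.683) and interneuron markers (0.123, adjusted p = 0.150) ended. With peaks near the gene end alone those for ELAV-like genes (odds ratio 11.6, exact adjusted p = 0.106), neuronal splicing regulators (2.05, adjusted p = 0.207), sympathoadrenal genes (3.14, adjusted p = 0.116) and ubiquitin genes (1.98, adjusted p = 0.188) ended. Excitatory neuron markers (0.0612, exact adjusted p = 0.0124) and oligodendrocyte markers (0.0871, adjusted p = 0.0401) then passed as lower. Cell cycle genes passed as higher with the stronger 50% (exact adjusted p = 0.0203), near the gene end (0.0134) and with every gene touched (0.00522). Axon growth genes did so with at least 2 N2A peaks (exact adjusted p = 0.0139) and with every gene touched (0.0133).

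The position of peaks along genes differed between the lists. In N2A 79.8% (78.8 to 80.8) of peaks in coding genes lay within 5 kb of the gene end, 5369 of 6727, against 19.7% (19.4 to 19.9) in cortex, 17911 of 91095. Peaks placed evenly along the same genes would give 20.4% and 7.77%. The median distance from peak to gene end was 1514 nt in N2A and 61077 nt in cortex. The first 5 kb of genes held 7.83% and 5.68%. In genes over 50 kb long the shares within 5 kb of the end were 70.9% in N2A and 11.9% in cortex, and in shorter genes 86.8% and 49.8%. Map1b and Snap25 had their strongest peaks near the gene end in both lists, whereas the strongest Fgf14 peak lay 603 kb from it.

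Stronger peaks lay nearer the gene end in both lists. In strength class 1 of 10, the strongest, 50.4% of cortex peaks and 92.0% of N2A peaks lay within 5 kb, and in class 10 the shares were 11.6% and 67.5%. The strongest cortex peaks, as many as N2A had, gave 54.8% (53.6 to 56.0), with a median distance of 3637 nt. Averaged per gene, these cortex peaks gave 73.5%, against 80.9% for all N2A peaks. With all peaks of both lists, the 2689 coding genes with peaks in both had a mean share per gene of 49.9% in cortex and 80.7% in N2A. The difference was -30.8 percentage points (bootstrap 95% interval over genes -32.2 to -29.4). The cortex share was lower in 1610 of these genes, higher in 264 and equal in 815. Gene spans include predicted transcript models and no exons, so intron and 3′ UTR peaks were not separated. With 1 list per group, tissue, list length and library preparation differed together.

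**Figure D2:**
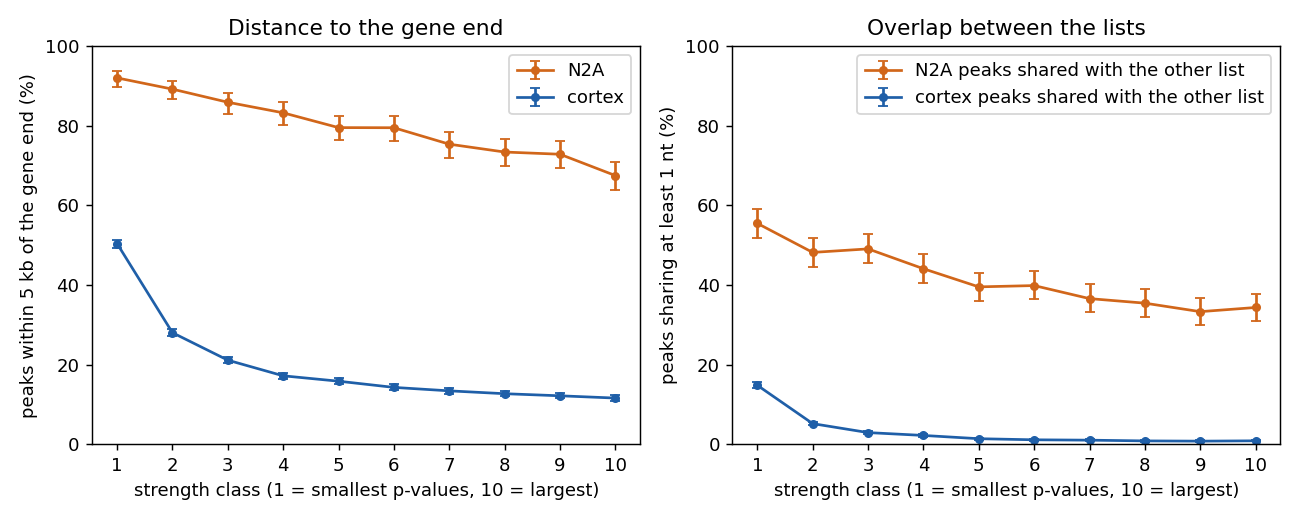
Left, percent of peaks in coding genes within 5 kb of the gene end, and right, percent of peaks with an overlapping peak in the other list, both by strength class from 1 (strongest) to 10 within each list, with Wilson 95% intervals. The share near the gene end ran from 50.4% to 11.6% in cortex and from 92.0% to 67.5% in N2A.

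At the level of single peaks, 3049 of 7335 N2A peaks overlapped a cortex peak on the same strand by at least 1 nt, 41.6% (40.4 to 42.7). In the other direction 3042 cortex peaks overlapped an N2A peak, 3.11% (3.004 to 3.222). The strongest peaks of Map1b, Atp2a2, Ywhaz and Scd2 lay at nearly the same coordinates in both lists. Of all their N2A peaks, 3 of 18, 2 of 7, 2 of 3 and 1 of 5 overlapped a cortex peak. The strongest Scd2 peaks lay at 44303393 to 44303443 in cortex and at 44303402 to 44303453 in N2A, on the plus strand of chromosome 19. The strongest Actb peaks did not overlap, at 142903477 to 142903528 in cortex and at 142903605 to 142903656 in N2A on the minus strand of chromosome 5. The cortex one also lay in the span of another gene, Gm38733. Of 2739 genes with peaks in both lists, the strongest N2A peak overlapped some cortex peak in 1511 (55.2%) and the strongest cortex peak in 882 (32.2%, 30.5 to 34.0). The strongest peaks lay within 1 kb of each other in 1775 genes (64.8%), and the median offset was 298 nt.

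The overlap was larger than random placement gave. For 6861 N2A peaks in genes with placements to draw from, 42.1% overlapped a cortex peak. The same peaks placed at random between the outermost peaks of their genes gave a mean of 7.82% (7.08 to 8.57 over 1000 placements), and placed anywhere in the gene 2.81%. For the 5369 peaks within 5 kb of a gene end, 41.5% overlapped, against 7.43% when they were placed at random in the last 5 kb. Peaks moved by 200, 500 and 1000 nt overlapped in 9.77%, 8.29% and 5.98%. The overlap was 55.4% in strength class 1 of N2A peaks and 34.3% in class 10, and 14.8% and 0.859% in cortex. With the strongest cortex peaks alone, as many as N2A had, 17.1% of N2A peaks overlapped one. Of the N2A peaks without an overlap 3970 lay in assigned genes, and 3552 of these (89.5%) lay in genes that had cortex peaks elsewhere.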

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

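The tests for different genes in the lists, for weak N2A peaks and for small offsets were chosen after the results they bear on had been seen. The 5 kb window, its test with the strongest cortex peaks and the comparison of both sides of genes were chosen after the lists had been seen. The strand test past gene ends was chosen after the downstream excess had been seen.

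Peaks outside the gene comparisons were noticed because they carry signal in regions that the report's comparisons leave out. On unplaced scaffolds there were 23 cortex and 14 N2A peaks. On the mitochondrial genome there were 29 cortex and 5 N2A peaks, and the strongest small RNA peak there lay in the cortex list in TrnM, a transfer RNA (p of 1.13e-240). Outside every gene span there were 3172 cortex and 272 N2A peaks. Within 10 kb past the end of Pex5l lay 7 of the cortex peaks and past that of Ago2, an Argonaute gene, 8, both genes chosen after their values were seen.

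Cortex peaks outside genes lay mostly on the downstream side when they were near a gene and on its strand. Within 10 kb, 1191 lay downstream of a gene on its strand and upstream of none, and 51 upstream and downstream of none, a ratio of 23.4 (17.6 to 31.5), where a chance position beside genes was set to give at most 1.5. With the 65 peaks near both sides counted on each, the counts were 1256 and 116, a ratio of 10.8, and in N2A the ratios were 14 (6.17 to 39.2) without the 10 such peaks and 5.88 with them. The same downstream peaks were also set against the opposite strand within 10 kb past gene ends, and 1201 cortex peaks lay on the gene's strand alone and 45 on the opposite strand alone, a ratio of 26.7 (19.8 to 36.8; in N2A 43, 11.5 to 361), which is consistent with the hypothesis of transcripts that run past the annotated gene end. Separate unannotated genes on the same strand stay open, and no biological difference between the groups was tested. The remaining 1865 cortex peaks lay on neither side of a gene on its strand. They can include peaks on the opposite strand near a gene, and peaks beside genes whose strand was not known from their peaks.

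Cortex peaks lay within 5 kb of the gene end less often than N2A peaks. With the strongest cortex peaks, as many as N2A had, the shares still differed by 25.0 percentage points (23.5 to 26.5). The cortex share rose from 19.7% to 54.8% in that test, so the length of the list may account for part of the difference. Averaged per gene, the strongest cortex peaks gave 73.5% and N2A 80.9%. That gap was under the 10 points set as the limit for list length. The shares of peaks argue against list length as the whole cause and the means per gene do not, so this stays open. Genes with peaks in both lists differed by 30.8 points (29.4 to 32.2) in the mean share per gene, which argues against different genes alone as the cause. The full cortex list was used there, 33147 peaks against 6354 in N2A. List length and different genes acting together were therefore not excluded. Brain tissue against cell line cannot be told apart from linker design, pooling and sequencing depth, since there was 1 list per group, and binding to introns was not tested.

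Most N2A peaks, 58.4%, had no overlapping cortex peak although the cortex list was longer. Weak N2A peaks as the whole cause are argued against by strength class 1 of 10, in which 44.6% (40.99 to 48.17) had none. The share without a cortex peak was 65.7% in class 10, so weak peaks may account for part. Genes without cortex peaks held 10.5% (9.61 to 11.5) of the unshared peaks in assigned genes, and allowing 50 nt between peaks left 48.3% (47.1 to 49.4) unshared, so neither could be the main cause. Different binding places within the same genes in tissue and in the cell line remain a possible explanation that was not tested, beside the depth of the lists and peak calling, and with 1 list per group a second library of the same kind was not there for comparison.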

How the results depend on the processing

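All alternatives to the share of peaks near the gene end, and those with peaks near the gene end alone or every gene touched, were chosen after the data were seen. The others were planned. Among results for single gene groups, 244 kept their direction and side of the threshold, 15 newly passed it, 21 no longer passed and 23 reversed. Among the main shares and counts 26 stayed within the limits set and 30 moved. The causes were not tested except where the construction of an alternative gives them, as for shorter lists or other windows. No paired analysis was possible because no list gives values per sample and N2A had 1 sample. Motifs, 3′ UTR peaks, regions by midpoint and leaving out cortex samples were not run. Unknown depth limits all comparisons of the lists.

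The stronger 50% of each list held 48887 and 3667 peaks. It gave a coding share of 93.4% in cortex, shares near the gene end of 26.5% in cortex and 86.0% in N2A, 1649 coding genes in both lists, and 2 groups lower in cortex, where cell cycle and ribosomal genes passed and microglia markers did not. Counting each gene once gave coding shares of 94.2% in cortex and 96.9% in N2A. That count leaves out peaks in several genes or in none, so its order cannot be set against that of the peak shares. A window of 2 kb gave 12.8% in cortex and 58.4% in N2A, and 10 kb gave 24.5% and 85.7%. Majority-strand peaks of genes with at least 3 peaks, a change of both strand and genes, gave 18.1% in cortex, the mean per gene 44.7% and 80.9%, and genes in both lists 49.9% in cortex. The share near the gene end stayed higher in N2A in each of these.

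The strongest cortex peaks gave 54.8% near the gene end, and a mean per gene of 73.5%, against 80.9% in N2A. They also gave 1501 coding genes in both lists, and overlaps of 17.1% of N2A and 17.0% of cortex peaks. Requiring 50% of the shorter peak gave 35.5% of N2A and 2.67% of cortex peaks, and allowing 50 nt gave 51.7% and 3.81%. Groups higher and lower in N2A against cortex numbered 3 and 8 with the strongest cortex peaks. None, 0, were lower with at least 2 N2A peaks, and 5 were lower with peaks near the gene end. With every gene touched 0 groups were lower in cortex.

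Odds ratios that reversed were not past the threshold, except for postsynaptic genes in N2A against the strongest cortex peaks (0.244, Fisher's exact adjusted p = 0.00318). Against all coding genes in cortex, sympathoadrenal genes reversed to 0.908 (stronger 50%) and 0.946 (every gene touched), and endothelial markers to 0.656 (stronger 50%) and 0.379 (near the gene end). In N2A the stronger 50% reversed oxidative phosphorylation to 0.978, excitatory markers to 1.196 and microglia markers to 1.40. In N2A against cortex, postsynaptic genes reversed to 0.461 (stronger 50%), 0.822 (at least 2 peaks), 0.710 (near the gene end) and 0.945 (every gene touched). The strongest cortex peaks reversed glutamate synthesis to 0.447, presynaptic genes to 0.446, microtubule genes to 0.605, axon growth to 0.730, oxidative phosphorylation to 1.64 and long noncoding RNAs to 0.366. At least 2 peaks reversed immediate early genes to 0.488 and small noncoding RNAs to 0.561. Peaks near the gene end reversed microtubule genes to 0.805 and immediate early genes to 0.937, and every gene touched reversed oxidative phosphorylation to 1.12. The cause was not tested.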

Other observations

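The genes in the next paragraphs were chosen after their values were seen, and no hypothesis was tested on them.

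Some genes ran against the greater length of the cortex list. Of 2739 genes with peaks in both lists, 211 (7.70%) had more N2A than cortex peaks, 375 had equal numbers and 2153 had fewer. Malat1, an abundant nuclear long noncoding RNA, had 15 N2A peaks and 3 cortex peaks, and 2 of the N2A peaks overlapped a cortex peak. Nucks1, a nuclear DNA-binding phosphoprotein, had 17 and 7. Slc7a1, a cationic amino acid transporter whose mRNA is an AU-rich ELAVL1 target, had 13 and 3, and all 13 lay within 5 kb of the gene end. Itga6, a laminin-binding integrin, had 8 and 2. Irf2bp2, a transcriptional corepressor, had 9 and 3, and 0 of its N2A peaks overlapped a cortex peak. Its strongest peaks lay at 126590826 to 126590877 in N2A and at 126590911 to 126590962 in cortex, both on the minus strand of chromosome 8. Cbx5, the heterochromatin protein HP1 alpha, had 20 N2A and 15 cortex peaks.

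Ube3a, the imprinted ubiquitin ligase of Angelman syndrome, had peaks on both strands in cortex and on 1 strand in N2A. Its span held 45 cortex peaks on the plus strand (best p of 6.60e-51) and 72 on the minus strand (best p of 1.68e-203). In N2A all 11 peaks lay on the plus strand (best p of 6.84e-26). The long noncoding RNA Snhg14, whose span overlaps that of Ube3a and which carries the antisense transcript of Ube3a, had 113 cortex peaks of its own, 98.2% on the minus strand (best p of 1.20e-278), and 0 N2A peaks. Peak assignment did not use strand, so the minus-strand peaks were counted for Ube3a in the cortex values. Wwox, an oxidoreductase, had 31 cortex peaks on the plus strand and 7 on the minus strand.

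Y RNAs, small RNAs bound by the Ro protein, had peaks in both lists at almost the same place. Rny3 had 1 peak in each, and Rny1 had 1 in each, at 47788078 to 47788129 in cortex (p of 6.55e-37) and at 47788070 to 47788121 in N2A (p of 3.32e-06) on the minus strand of chromosome 6. Rn7sk, the RNA that restrains the elongation factor P-TEFb, had cortex (p of 3.29e-26) and N2A (p of 0.0164) peaks as well. Reads of such RNAs can align to several copies in the genome, and the lists do not show how those were handled.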
